A study of Mus musculus with 2 samples.

How the data were processed

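The values are UMI counts per gene and droplet barcode as deposited, for all barcodes and before any cell calling, made with Cell Ranger 4 per the file headers and with the mm10 genome per the submitters' processing notes. Per the labels' protocols, forebrains at embryonic day 18.5 were dissociated with papain, 2 forebrains were pooled for each library, and droplet libraries were made with 10x chemistry. The gene annotation release and the other settings of the counting step are not given in the sources used here. No cell labels or clusters of the authors were used. The counts were checked to be whole numbers, with the same genes in the same order in both libraries. Single cells are not replicates, so each group has 1 library and no test between the groups was made.

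A barcode was called a cell with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from mitochondrial transcripts, which gave 9086 wild-type and 12855 knockout-labelled cells. Doublets were scored with Scrublet within each library, and the cells with the highest scores were left out at a rate of 0.8% per 1000 called cells, which removed 660 (7.26%) and 1322 (10.3%). The automatic threshold of Scrublet would have removed 231 (2.54%) and 529 (4.12%). The kept cells hold 97252176 and 109610220 UMIs.

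Counts per cell were scaled to 10000 and log-transformed, 2000 variable genes (without Cyfip2, Xist, Tsix, Y-linked, mitochondrial, ribosomal protein and haemoglobin genes) and 30 principal components were taken, and a graph of 15 neighbours was clustered with the Leiden method at resolution 1, which gave 30 clusters. Libraries were not aligned to each other. Each cluster was named from 24 fixed sets of marker genes. It took the family whose markers had the highest mean scaled level, of at least 0.75, provided that at least 3 of its markers were at least 1.5-fold higher than in other clusters. At least 50% of its cells also had to carry a UMI of 3 or more family markers, and no other family could have more markers among the 10 leading genes of the cluster. A class name within the family needed in addition at least 1 marker of its own among those 10 genes. A cluster with a family but no class keeps its number, and 2 clusters stayed unnamed. This naming rule was set and revised after the clusters and some of the comparisons had been seen, because cluster 20 had dominated the comparison of migrating neurons and cluster 19 had been named from few cells.

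For each class the UMIs of all its cells were summed per library and divided by the summed UMIs of that class, and scaled, and is given as CPM. A gene was measured with at least 20 CPM in either library and at least 100 counts in both together. Ratios are of the knockout-labelled over the wild-type library, with exact 95% intervals for a ratio of Poisson counts, which cover counting error only. A gene is called higher or lower at a log2 ratio of at least 0.58 in size, which is 1.5-fold, and an interval that leaves out 1, as a rule of size and not a test. The named genes of each main comparison are the 12 with the largest ratios in each direction among the measured genes called by this rule, and 3 in each direction for every other class of at least 50 cells in each library. Cajal-Retzius cells needed at least 20 cells. Xist, Y-linked, haemoglobin and mitochondrially encoded genes and unnamed transcripts were counted but not named. A gene without counts in 1 library is given a bound, from a floor of 3 counts. Equal cluster weights means that CPM is averaged over the clusters of a class with the same weight for each cluster in both libraries, which removes differences in mixture between clusters. A gene then counts by its weighted ratio, with the interval of the unweighted ratio on the same side. Shares of cells with a UMI were taken after thinning every cell to 1000 UMIs.

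Expression-matched lists were used to place 22 lists of genes fixed before the data were examined: the WAVE regulatory complex, actin regulators, partners of FMRP and translation control, Reelin signalling, neuronal migration, axon guidance, the synapse, transcription factors of neuron subtypes, DNA replication, mitosis, Notch and progenitor maintenance, Wnt signalling, targets of p53, immediate early genes, heat shock, hypoxia and glycolysis, integrated stress and the unfolded protein response, mitochondrially encoded transcripts, nuclear-encoded oxidative phosphorylation, cholesterol biosynthesis, interferon response, and long neuronal genes of cell adhesion. The median log2 ratio of each list was placed among those of 10000 random lists drawn from the same 20 expression bins. Lists with 2 or fewer measured members were not placed, and those placed in the main comparisons had at least 4. The percentile describes these 2 libraries and is not a test. A member counts as above or below 0 when its counting interval lies there.

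The rules were tested on simulated data, drawn as Poisson counts from the mean profile of both libraries for each comparison, with fold changes planted in known genes. Variation between embryos and between cells is not part of this simulation, so its numbers of false calls hold for counting error only. For excitatory neurons (6701 genes), GABAergic neurons (6765) and progenitors (6742), 67 of 67 genes changed 2-fold and 66 of 66 changed 4-fold were called, 0 of 67 changed 1.2-fold were called, and 0 of 6501, 6565 and 6542 unchanged genes. For Cajal-Retzius cells (3657 genes), 61 of 67 (91.0%) changed 2-fold, 53 of 66 (80.3%) changed 4-fold, 6 of 67 (8.96%) changed 1.2-fold and 32 of 3475 (0.921%) unchanged genes were called. The synapse list, with a planted 1.2-fold change, stood at percentile 100 in all 4 comparisons. Over 20 repeats without any change, the mean number of lists outside the central 95% was 0.7 in excitatory neurons, 1.3 in GABAergic neurons, 1.25 in progenitors and 1.1 in Cajal-Retzius cells, with at most 4, 4, 3 and 4. These repeats replaced a smaller trial after 4 of 20 unchanged lists had fallen outside in progenitors.

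Free RNA was profiled from barcodes with fewer than 100 UMIs, and as an alternative from those with 100 to under 500. Its share was the one that leaves haemoglobin transcripts at 0 in neurons, which gave 2.73% and 2.63% of neuron UMIs under the lower profile and 1.43% and 3.53% under the other. The main values are not corrected for it. Alternative settings were fixed before the files were opened, except equal cluster weights, leaving out clusters of uneven share, and the free RNA profile from 100 to under 500 UMIs, which were chosen after seeing the data. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.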

Results

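Forebrain cells of mouse embryos at embryonic day 18.5 were profiled in 2 droplet libraries, 1 labelled wild type and 1 labelled Cyfip2 knockout, each from a pool of 2 forebrains. Cyfip2 encodes a subunit of the WAVE regulatory complex, which links Rac signalling to branched actin assembly in growing neurons. The comparison asks which cells make up the forebrain and which genes differ within them when this gene is targeted. The libraries held 123978461 and 150828048 UMIs, and 8426 wild-type and 11533 knockout-labelled cells were kept. These had medians of 9567 and 7787 UMIs and of 3374 and 2960 genes per cell. Values are given with the wild-type library before the knockout-labelled library. A number in parentheses after a gene or its CPM is the log2 ratio of the knockout-labelled over the wild-type library, and a value that follows it is that ratio with equal cluster weights, unless named otherwise. A value given for a list is its median log2 ratio. No difference between the libraries has a replicate check, and intervals are 95% intervals that cover counting error only, since UMIs of 1 cell and cells of 1 embryo are not independent samples.

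The tags of Cyfip2 did not drop in the library labelled Cyfip2 knockout. The gene (ENSMUSG00000020340) lies on the minus strand of chromosome 11, from 46193850 to 46312859 in mm10. Over all cells the gene was at 84.9 CPM (83.0 to 86.7; 8253 UMIs) in wild type and 84.4 CPM (82.7 to 86.1; 9247 UMIs) in the knockout-labelled library. The targeted part of the gene and the positions of the reads are not given in the sources used here. A tag counted at the end of a transcript checks nothing where the deleted part lies elsewhere, so the genotype of the library rests on its label. What differed was the distribution over cell types. In wild type the gene was highest in neurons among the 15 classes of at least 50 cells in each library: its level ran from 3.69 CPM in microglia to 124 CPM in cluster 12 of the excitatory neurons, a 33.7-fold range. In the knockout-labelled library the same classes ran from 46.5 to 104 CPM, a 2.23-fold range, though the smaller groups of vascular cells (125 CPM) and Cajal-Retzius cells (154 CPM) lay above it. The paralogue Cyfip1 kept its range, 8.29-fold and 8.22-fold, with 52.7 and 51.3 CPM over all cells.

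Cyfip2 was slightly lower in the knockout-labelled library in excitatory and GABAergic neurons as whole groups, and higher in progenitors, microglia, vascular, meningeal (38.1 and 74.5 CPM, 0.97, 0.08 to 1.94) and Cajal-Retzius cells. The few cells of the oligodendrocyte lineage were level, at 109.5 and 106 CPM (15 and 13 UMIs). In excitatory neurons it was at 103 CPM (100.2 to 105) and 92.7 CPM (90.3 to 95.1), a log2 ratio of -0.15 (-0.20 to -0.10), and in GABAergic neurons at 85.7 and 78.5 CPM (-0.13; -0.23 to -0.02). In progenitors it was at 35.5 CPM (32.9 to 38.4) and 62.4 CPM (58.9 to 66.1), a log2 ratio of 0.81 (0.67 to 0.95), or 0.83 with equal cluster weights. Microglia went from 3.69 CPM (1.00 to 9.45; 4 UMIs) to 46.5 CPM (37.2 to 57.3; 87 UMIs), and vascular cells from 15.1 CPM (6 UMIs) to 125 CPM (143 UMIs). Within the neurons, interneurons of the medial ganglionic eminence (-0.47), cluster 12 (-0.56) and deep-layer neurons (-0.30) were lower, while migrating neurons (0.21), striatal neurons (0.11, -0.05 to 0.28) and interneurons of the caudal or lateral eminence (0.17) were not. Within the progenitors, radial glia were at 22.7 and 54.6 CPM (1.26; 0.93 to 1.60) and the dividing cells of cluster 14 at 29.2 and 68.4 CPM (1.23), but intermediate progenitors at 63.3 and 65.5 CPM (0.05). After thinning every cell to 1000 UMIs, a Cyfip2 UMI was seen in 9.71% and 9.25% of excitatory neurons, 3.86% and 7.81% of progenitors and, as a cell type that should lack the gene, in 0% of wild-type microglia (up to 5.28% by its interval at that depth) and 5.63% of the others. Unthinned, these shares were 61.6% and 53.7%, 33.7% and 50.6%, and 5.88% and 37.3%, at median depths of 10594 and 8702 UMIs in excitatory neurons, 15330 and 13091 in progenitors and 15517 and 12676 in microglia. Of 22 measured genes within 5 Mb of Cyfip2 on chromosome 11, none differed 1.5-fold over all cells, with log2 ratios from -0.10 (Rnf130) to 0.28 (Ebf1). Within excitatory neurons Ebf1 did pass the size rule, at 0.89.

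**Figure D1:**
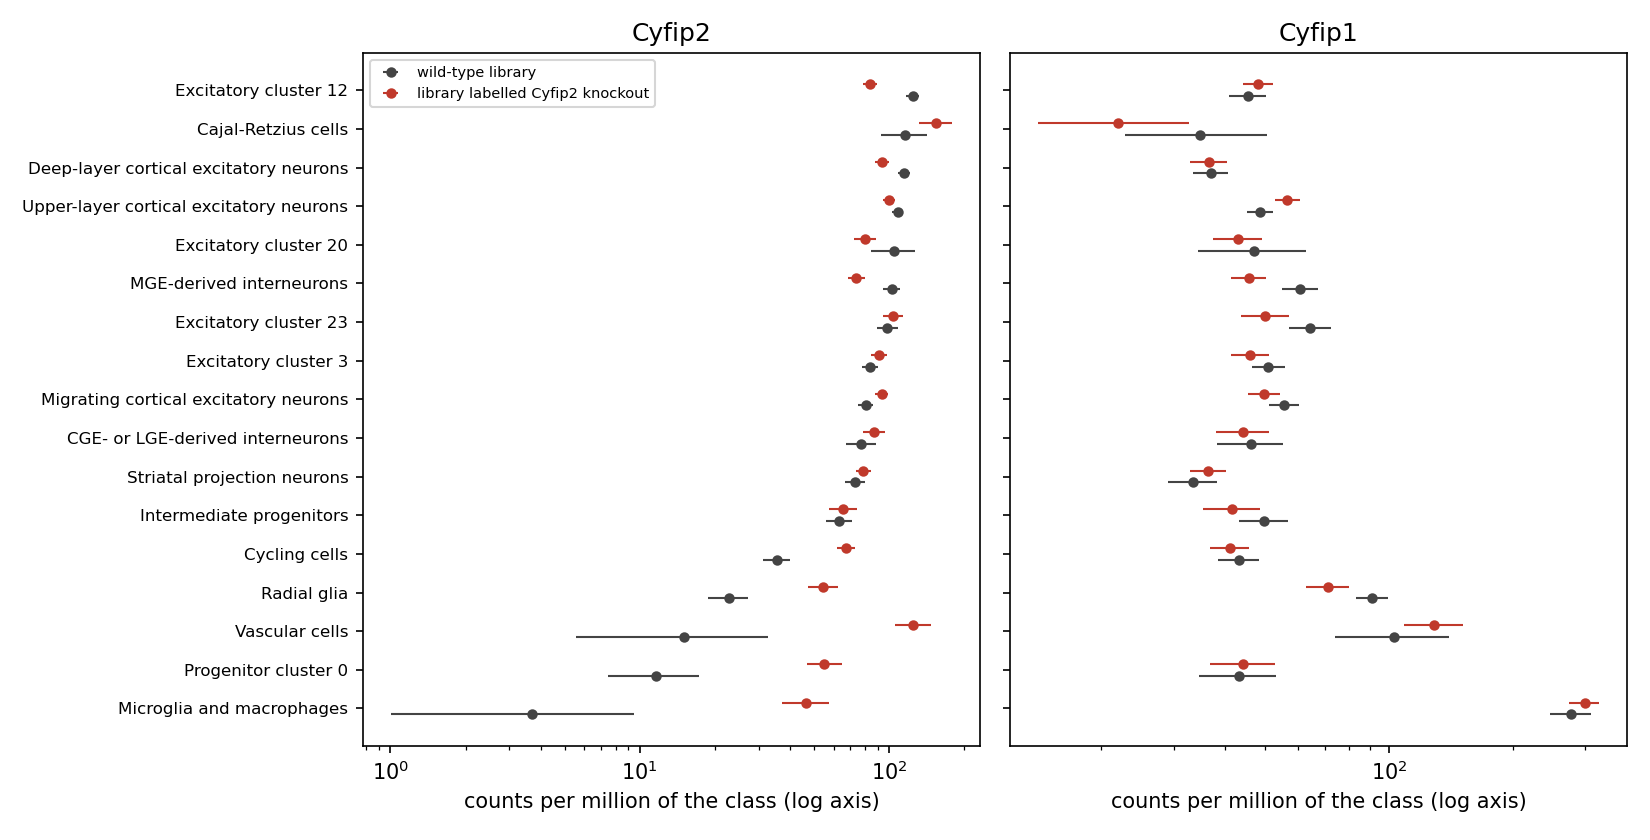
Level of Cyfip2 and of its paralogue Cyfip1 in each cell class of the wild-type and the knockout-labelled library. Bars are exact Poisson intervals, which cover counting error only.

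The neuronal partners of Cyfip2 in the WAVE complex moved little, while Nckap1l and Abi3 had almost no counts outside microglia. In excitatory neurons Wasf1, the neuronal WAVE protein, was at 92.8 and 79.5 CPM (-0.22), Nckap1, the subunit that binds Cyfip directly, at 126 and 118 CPM (-0.09), and Brk1, the small stabilising subunit, at 148 and 138 CPM (-0.10). Abi2 was level, at 121 and 124 CPM (0.03). In progenitors Cyfip1 (58.2 and 48.0 CPM, -0.28), Abi1 (45.5 and 38.3 CPM, -0.25), Nckap1 (-0.13) and Brk1 (-0.12) were lower, while Cyfip2 was higher. The intervals of Wasf1 (-0.06), Wasf2 (-0.08) and Abi2 (0.02) included 0 there. Cyfip1 was lower in radial glia (-0.36), which had a lower share of cells, and level in dividing progenitors (-0.07). In GABAergic neurons Cyfip1 was at 46.6 and 41.3 CPM (-0.18). As a list, the complex without Cyfip2 lay inside the central 95% of matched lists in excitatory neurons (median log2 ratio -0.06), GABAergic neurons (-0.05), progenitors (-0.12; percentile 4.51) and Cajal-Retzius cells (-0.02). With equal cluster weights it was at -0.05 (percentile 25.15) in progenitors.

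The forebrain libraries consist of cortical excitatory neuron-like cells, GABAergic neuron-like cells and progenitor-like cells, with small groups of Cajal-Retzius-like, microglia-like, vascular-like, meningeal-like and oligodendrocyte-lineage-like cells. These names rest on marker genes and are used below in short form. In the knockout-labelled library the share of GABAergic neurons was higher and the shares of excitatory neurons and radial glia were lower. Excitatory neurons made up 56.7% (55.6 to 57.8) and 51.6% (50.7 to 52.5) of cells, GABAergic neurons 24.9% (23.9 to 25.8) and 31.4% (30.6 to 32.3), and progenitors 14.1% (13.4 to 14.9) and 12.3% (11.7 to 12.9). Cajal-Retzius cells were 0.451% and 0.512%, microglia 0.807% (0.627 to 1.02) and 1.23% (1.04 to 1.45), vascular cells 0.392% and 0.598%, meningeal cells 0.214% and 0.286%, and the oligodendrocyte lineage 0.119% and 0.139%. These shares also carry the dissection and dissociation of 1 pool per label, and median depth was lower in the knockout-labelled library, 8702 against 10594 UMIs in excitatory and 6041 against 7050 UMIs in GABAergic neurons.

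The excess of GABAergic neurons was largest for striatal projection neurons, 10.1% and 14.3% of cells, a ratio of 1.42 (1.30 to 1.54). Interneurons of the caudal or lateral ganglionic eminence had a ratio of 1.29 and those of the medial ganglionic eminence 1.09 (0.992 to 1.19). Of 7 GABAergic clusters 5 were more frequent and 2 less, among them cluster 16 with a ratio of 0.898 (0.809 to 0.997). Single clusters carried much of the excess: cluster 2 (Sst, Lhx8, Nkx2-1 and Zic1) was 1.96 times and striatal cluster 17 (Isl1, Zfp503 and Ebf1) 2.25 times as frequent. On the excitatory side 8 of 10 clusters were less frequent, with ratios of 0.836 for upper-layer, 0.749 for deep-layer and 0.817 for migrating neurons. The exceptions were cluster 12, with 5.45% and 6.01% of cells (ratio 1.10), and cluster 20, led by Tfap2d, Thsd7a and Nrp2, with 124 and 639 cells (1.47% and 5.54%; ratio 3.77). Cluster 20 entered the excitatory family narrowly, at a mean scaled marker level of 0.79 (minimum 0.75). Neither it nor cluster 12 had a family marker among its 10 leading genes. A cluster mostly of 1 library can be a feature of that library and not a cell type. Radial glia were 4.0% and 2.43% of cells, a ratio of 0.607 (0.516 to 0.713) and intermediate progenitors 3.56% and 2.87% (0.806). Dividing cells were level in total (1.05), with cluster 14 higher (1.21; 1.04 to 1.41) and cluster 7 lower (0.709; 0.554 to 0.907). Cluster 14 carries ganglionic eminence markers and cluster 7 cortical ones: Dlx2 was at 537 and 5.94 CPM in them, and Eomes at 6.10 and 504 CPM. Cluster 0, with eminence progenitor markers, had a ratio of 1.14 (0.909 to 1.43). Within the immune cells, macrophage cluster 27 (Pf4 and Mrc1) was 1.91 times as frequent.

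**Figure D2:**
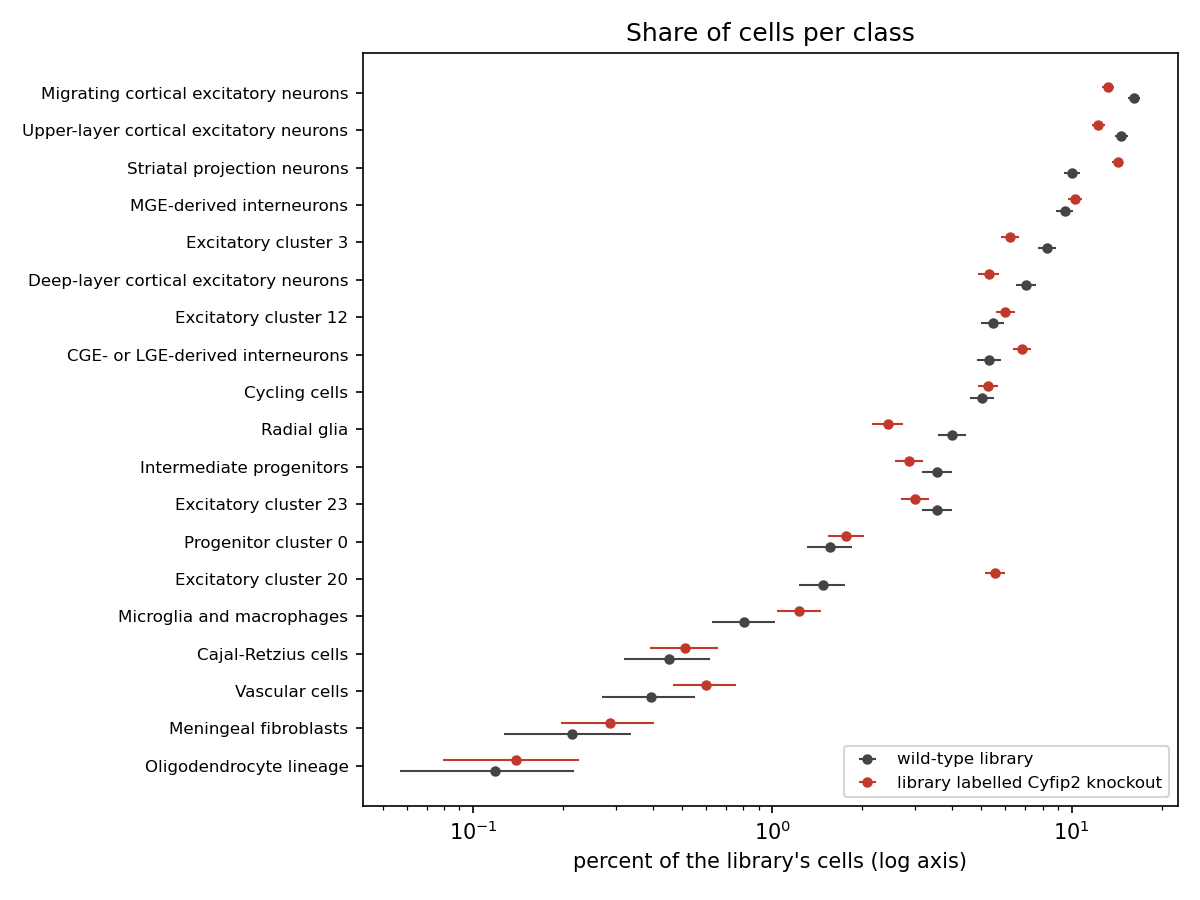
Share of kept cells in each class of the wild-type and the knockout-labelled library. Bars are exact binomial intervals, which cover counting error only.

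Few genes differed past the size rule in excitatory neurons as a whole, and more within some clusters. Of 6766 measured genes 10 were at least 1.5-fold higher and 5 lower in the knockout-labelled library, and with equal cluster weights 4 higher and 2 lower. With other scalings the split was 11 higher and 4 lower (median-of-ratios size factor) and 14 and 4 (without mitochondrial, haemoglobin and ribosomal protein genes). It was 3 and 5 where genes were centred within each library before clustering, which changes the clusters and not the scaling. Among the higher genes, 5 are leading genes of the more frequent cluster 20: Thsd7a (10.9 and 33.4 CPM, log2 ratio 1.62), the transcription factor Tfap2d (1.57), the semaphorin receptor Nrp2 (0.84), Zfp703 (0.77) and the Notch ligand-like receptor Dner (0.65). With equal cluster weights Thsd7a and Tfap2d were each at 0.14 and Dner at 0.07, whereas Nrp2, which also leads cluster 23, was at 0.51, but at -0.056 with clusters of resolution 2, and Zfp703 was at 0.41. Thsd7a reversed with a mitochondrial maximum of 5% (-0.087), with genes centred within each library (-0.16) and without the clusters of uneven share (-0.15).

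Other genes kept most of their difference within clusters. Id4, an inhibitor of neurogenic helix-loop-helix factors, was at 38.5 and 94.3 CPM (log2 ratio 1.30, 0.83 with equal cluster weights). Zic1, a zinc finger factor of septal and medial forebrain lineages, was at 22.2 and 45.2 CPM (1.03; 0.94), and Ebf1, a factor of striatal neurons, at 11.2 and 20.8 CPM (0.89; 0.52). Zic1 is a leading gene of cluster 2 and Ebf1 of clusters 8 and 17. Neither Zic1 nor Id4 was particular to excitatory neurons. Among the 14 classes of at least 100 cells in each library, the Zic1 interval lay above 0 in 11 and below in 1. For Id4 these were 8 and 2. Zic1 was also higher in barcodes with fewer than 100 UMIs (39.7 and 61.1 CPM, 0.62). Lmo3, a LIM-only cofactor of deep layers, was at 39.0 and 59.8 CPM (0.62; 0.54). Ttr, the thyroxine carrier made by choroid plexus, was at 26.3 and 80.3 CPM (1.61), and leads unnamed cluster 19. Its excess depended on free RNA. After subtracting the profile under 100 UMIs -1.45 and 25.9 CPM were left, but 6.90 and -5.38 CPM under that from 100 to under 500 UMIs. On the lower side stood Nts, the neurotensin precursor (46.0 and 22.6 CPM, -1.03; -0.85), Crym, a thyroid hormone-binding protein of deep layers (33.7 and 21.2 CPM, -0.66), Igfbp3, which binds insulin-like growth factors (21.6 and 13.6 CPM, -0.66), and Slc1a3, the glial glutamate transporter (31.0 and 20.7 CPM, -0.59). Nts leads clusters 4 and 21, and Crym and Igfbp3 lead cluster 21.

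Metabolic and protein-folding lists were higher and migration and cholesterol lists lower in excitatory neurons. Of 21 measured lists 5 lay above and 4 below the central 95% of 10000 matched lists. With equal cluster weights these were 5 and 4, not all of them the same lists. About 1.05 of 21 lists of independently drawn genes would fall outside. Genes of 1 list can vary together, so this number does not measure what chance gives for the lists. All 12 mitochondrially encoded transcripts were higher (median 0.13; percentile 100), such as mt-Co2 (3574 and 3994 CPM, 0.16) and mt-Nd4l (0.20). Of 16 genes of the unfolded protein response 9 were higher and 1 lower (0.10), with the chaperones Hsp90b1 (239 and 278 CPM, 0.22), Hspa5 (0.19), Sdf2l1 (0.32) and Creld2 (0.26). Hypoxia and glycolysis (0.08; 13 of 22 higher, 1 lower) included Egln1 (0.22), Higd1a (0.18) and Pfkp (0.18), and oxidative phosphorylation (0.04; 26 of 36 higher, 3 lower) included Uqcrb (256 and 283 CPM, 0.14) and Cox8a (0.13). Long adhesion genes were at 0.02 (percentile 98.2), with Lrp1b (0.31) and Cdh12 (0.30) higher and Kirrel3 (-0.24) lower.

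The migration list had a median of -0.09 (percentile 0), with 17 of 27 members lower and 2 higher. Flrt3, a receptor of radial and tangential spread (81.1 and 58.1 CPM, -0.48), the semaphorin receptor Nrp1 (329.5 and 279 CPM, -0.24) and the Rac exchange factor Tiam2 (199 and 171 CPM, -0.22) were lower. Cholesterol biosynthesis had 13 of 16 members lower and 0 higher (-0.08; percentile 0.2), led by Insig1 (-0.23) and including Lss (-0.19). Actin regulators were at -0.04 (19 of 38 lower, 5 higher; percentile 0.73), with Arpc4 (-0.23), Baiap2, which binds Rac and WAVE (-0.20), Pak3 (-0.19) and Actb (8488 and 7585 CPM, -0.16), and subtype transcription factors at -0.05 (15 of 28 lower, 7 higher; percentile 0.23). Fezf2, which specifies corticospinal neurons (109 and 80.1 CPM, -0.45), and Nfix (-0.27) were lower, and Tbr1 (148 and 192 CPM, 0.37) and Bcl11b (0.28) higher. With equal cluster weights these last 2 lists moved inside, at percentiles 9.36 and 18.2, while Reelin signalling (-0.08; percentile 0.21) and axon guidance (-0.05; percentile 0.44) moved below the central range. Inside the central range without these weights were FMRP partners (-0.02), Reelin signalling (-0.05), axon guidance (-0.04), the synapse (-0.04), DNA replication (-0.02), mitosis (-0.02), Notch (-0.04), Wnt (-0.04), p53 targets (0.02), immediate early genes (-0.05) and heat shock (0.01).

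**Figure D3:**
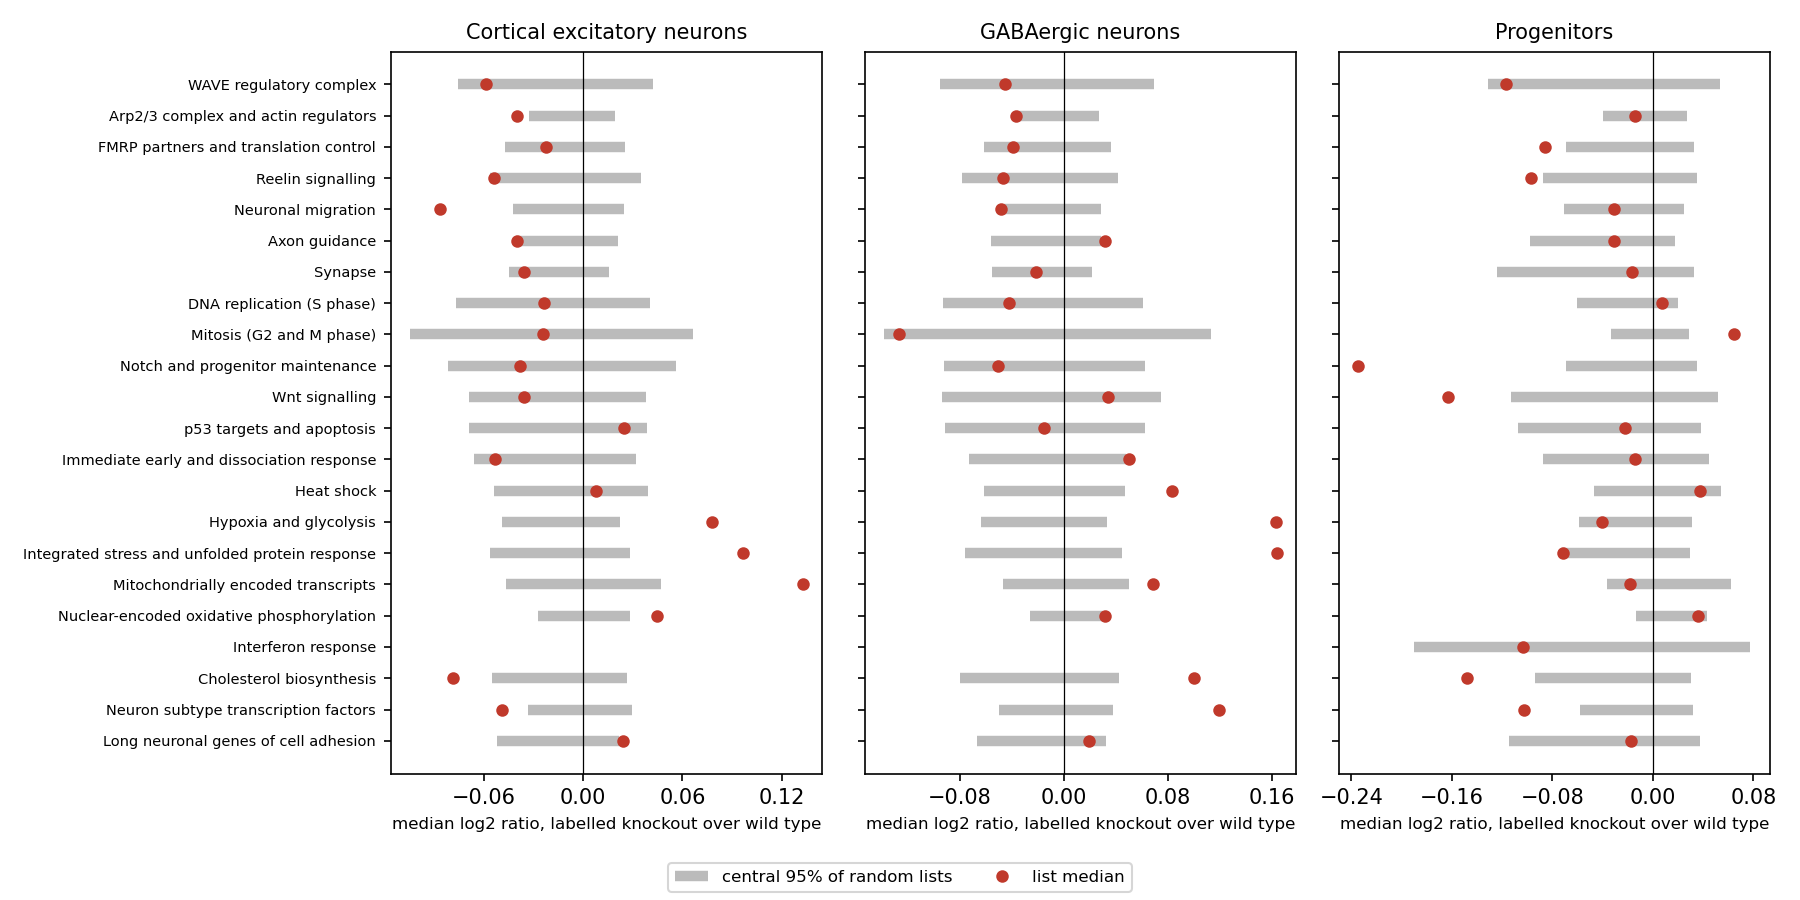
Median log2 ratio of each gene list in excitatory neurons, GABAergic neurons and progenitors, knockout-labelled over wild-type library. Grey bars are the central 95% of expression-matched random lists, as a description of these 2 libraries.

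The classes of excitatory neurons shared some of their leading genes, such as Ttr in 6 of them, and no difference between classes was tested. In upper-layer neurons Lmo3 (15.4 and 36.0 CPM, 1.22) and the peptide precursor Npy (53.3 and 104 CPM, 0.96) were higher, and Tshz3 (27.3 and 8.86 CPM, -1.62), the cholecystokinin precursor Cck (-1.09) and the neurofilament Nefl (-0.95) lower. In deep-layer neurons the Wnt antagonist Sfrp2 (11.2 and 33.9 CPM, 1.60) and the cadherin Cdh4 (0.90) were higher, and Fosl2 (42.0 and 16.9 CPM, -1.31), Nts (242 and 119 CPM, -1.02) and Kctd4 (-0.65) lower. Migrating neurons held more Zic1 (40.7 and 71.7 CPM, 0.82) and Ebf1 (0.82) and less Tac2 (-0.65). Cluster 12 held more Bcl11b, a deep-layer and striatal factor (52.9 and 107 CPM, 1.02), and Id4 (0.85), and less Mid1 (-0.80), Srr (-0.72) and Nr4a3 (-0.70). Cluster 3 held more Id4 (51.9 and 104 CPM, 0.99) and Cdh11 (0.74) and less Mid1 (-0.89), Nedd9 (-0.83) and the teneurin Tenm3 (81.4 and 49.1 CPM, -0.73). In cluster 23, with 41 genes higher and 72 lower, gastrin-releasing peptide, Grp, was lower (39.0 and 9.68 CPM, -2.01). In cluster 20, with 250 genes higher and 310 lower, the calcium-binding Calb2, Pcdh20 and the striatal phosphoprotein gene Ppp1r1b had 0 counts in wild type and 30.1, 25.3 and 31.5 CPM in the knockout-labelled library, at least 9.63-fold, 8.09-fold and 10.1-fold by a floor of 3 counts, while Rai14 (-2.07), Syt6 (-1.88) and Plekhf2 (-1.76) were lower.

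Scg2, Nrp2 and peptide precursor genes were among the genes that differed in GABAergic neurons. Of 6831 measured genes 33 were at least 1.5-fold higher and 8 lower in the knockout-labelled library, and with equal cluster weights 16 and 6. Several higher genes lead clusters 2 and 17, which were more frequent there: Scg2, a secretogranin of dense-core vesicles (9.93 and 36.0 CPM, log2 ratio 1.86, 1.39 with equal cluster weights), the imprinted Nap1l5 (84.1 and 154 CPM, 0.87; 0.64), the huntingtin partner Hap1 (21.2 and 37.4 CPM, 0.82; 0.26) and the neuropeptide Y receptor Npy1r (12.5 and 27.1 CPM, 1.12; 0.61). At resolution 0.5 Nap1l5 (-0.023) and Hap1 (-0.31) reversed. The peptide precursors of striatal output neurons, Tac1 (11.6 and 22.1 CPM, 0.93; 1.07) and Penk (17.9 and 31.7 CPM, 0.83; 0.84), were higher within clusters too, and lead clusters 8 and 18. Nrp2, which keeps interneurons out of the striatum, was at 27.0 and 65.8 CPM (1.28; 0.68). Higher also were Chchd10 of the mitochondrial intermembrane space (1.17), the adhesion genes Pcdh11x (1.03) and Tenm1 (40.8 and 72.0 CPM, 0.82), the protease inhibitor Serpine2 (1.01) and Mgat4c (0.84).

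Lower in GABAergic neurons were carbonic anhydrase Car2 (20.8 and 10.3 CPM, -1.02; -0.70), the retinoic acid-binding Crabp1 (36.1 and 20.6 CPM, -0.81; with 27.9% of its wild-type counts in 1 cell), the microtubule-binding ubiquitin ligase Mid1 (39.3 and 23.7 CPM, -0.73; -0.76), Epb41l4a (-0.68), thrombospondin Thbs1 (40.5 and 25.3 CPM, -0.68), the chemokine receptor of tangential migration Cxcr4 (54.8 and 34.6 CPM, -0.67) and Frmd6 (-0.65). With equal cluster weights Cxcr4 was at -0.25 and Thbs1 at -0.23. By class, striatal neurons had more Nrp2 (11.8 and 58.9 CPM, 2.32), the Reelin adaptor Dab1 (10.7 and 29.1 CPM, 1.44) and Ptprt (1.42), with Crabp1 (-0.83), Frmd6 (-0.73) and Prc1 (-0.63) lower. Medial eminence interneurons, among which cluster 2 was more frequent, had more Scg2 (2.70; 2.00) and the calcium channel subunit Cacna2d1 (5.50 and 21.9 CPM, 2.00; 1.29), and less Mid1 (34.0 and 16.6 CPM, -1.03) and Car2 (-1.0). In that class 102 genes were higher and 36 lower, and 24 and 18 with equal cluster weights. Interneurons of the caudal or lateral eminence had more Zic1 (15.0 and 66.4 CPM, 2.15) and the netrin receptor Dcc (21.9 and 55.9 CPM, 1.35), and less Micall1 (-0.96), Ankmy1 (-0.89) and Ddi2 (-0.88).

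Stress, glycolysis and cholesterol lists were higher in GABAergic neurons, so that cholesterol genes ran opposite to excitatory neurons. Of 21 measured lists 9 lay above and 2 below the central range, and with equal cluster weights 4 and 2. Cholesterol biosynthesis had 9 of 14 members higher and 0 lower (median 0.10), such as Msmo1 (53.8 and 66.2 CPM, 0.30) and Nsdhl (0.22). The unfolded protein response (0.16; 10 of 15 higher, 1 lower) included Hsp90b1 (206 and 247 CPM, 0.26), Creld2 (0.30) and Asns (0.28), and heat shock (0.08; 7 of 12 higher, 1 lower) Hspa8 (0.17) and Hsph1 (0.17). Hypoxia and glycolysis (0.16; 16 of 22 higher, 0 lower) included Gpi1 (68.4 and 87.3 CPM, 0.35), Ldha (66.9 and 84.0 CPM, 0.33) and P4ha1 (0.40). Mitochondrially encoded transcripts (0.07), oxidative phosphorylation (0.03), immediate early genes (0.05; Fos 0.22, Junb -0.22) and axon guidance (0.03; Dcc 0.59, Sema3a 0.40) were also above, but with equal cluster weights all 4 moved inside, at percentiles 68.7, 97.2, 83.3 and 97.3. Subtype transcription factors (0.12; 13 of 20 higher, 6 lower), with Neurod6 (27.0 and 45.0 CPM, 0.74), Rorb (0.59) and Cux2 (199 and 142 CPM, -0.49), changed sign with equal cluster weights (-0.03). Below were neuronal migration (-0.05; 11 of 28 lower, 6 higher), with Ackr3 (82.7 and 56.7 CPM, -0.55) and Erbb4 (134 and 109 CPM, -0.29), and actin regulators (-0.04; 15 of 37 lower, 2 higher), with Srgap2 (-0.26) and Rac1 (173 and 151 CPM, -0.20). Migration reversed with no filter but 1 count (0.011), and oxidative phosphorylation with thinned cells (-0.033). Inside were FMRP partners (-0.04), Reelin signalling (-0.05), the synapse (-0.02), DNA replication (-0.04), mitosis (-0.13), Notch (-0.05), Wnt (0.03), p53 targets (-0.01) and long adhesion genes (0.02).

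Progenitors of the knockout-labelled library held less of the Notch and progenitor maintenance list, beside a lower share of radial glia. These results are not independent, since Hes1, Hes5, Pax6, Sox2, Nes, Vim and Fabp7 are in both the list and the radial glia markers. Of 6838 measured genes 12 were at least 1.5-fold higher and 17 lower, and with equal cluster weights 3 and 4. With a median-of-ratios size factor the split was 15 higher and 14 lower. Lower were the matrix protein of the radial glial niche Tnc (119.5 and 65.5 CPM, log2 ratio -0.87, -0.49 with equal cluster weights), the receptor Notch2 (65.5 and 41.6 CPM, -0.65; -0.35), its target Hey1 (22.0 and 14.3 CPM, -0.62), the inhibitor of differentiation Id3 (64.7 and 40.8 CPM, -0.67) and the lysophosphatidic acid receptor Lpar1 (31.5 and 20.5 CPM, -0.62). Tesc, which binds the sodium-proton exchanger (24.5 and 12.1 CPM, -1.02; -0.77), Tmem132b (40.7 and 22.3 CPM, -0.87), the neutral amino acid transporter Slc1a4 (-0.73), Tnfrsf19 (-0.84), Tbc1d4 (-0.73), Scrg1 (-0.69) and Tanc1 (-0.67) were lower as well. Without the clusters of uneven share Id3 (0.42) and Scrg1 (0.91) reversed. Higher were Dlx6 (26.5 and 43.3 CPM, 0.71), its antisense Dlx6os1 (141 and 231 CPM, 0.71), the neurexin Nrxn3 (162 and 247 CPM, 0.61) and the vesicular transporter Slc18a2 (29.8 and 54.0 CPM, 0.86), and Tshz2 (1.05), Olig1 (40.5 and 70.0 CPM, 0.79) and Islr2 (0.74). Olig1 was seen in only 88 and 95 progenitors. Dlx6os1, Nrxn3 and Slc18a2 lead cluster 13, Tshz2 cluster 17, Tnc cluster 1 and Olig1 clusters 0 and 26, and with equal cluster weights Dlx6 was at 0.32 and Nrxn3 at 0.25. Ttr was at 28.9 and 61.6 CPM (1.09), with 22.0% of the wild-type counts in 1 cell, and reversed with a minimum of 2000 UMIs per cell (-2.22).

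Of 22 lists in progenitors 6 lay below and 1 above the central range, and with equal cluster weights 4 and 5. In total 12 lay outside with 500 UMIs and 250 genes, 11 with the automatic doublet threshold and 14 with no doublets left out. Notch and progenitor maintenance was lowest (median -0.23; percentile 0), with 14 of 19 members lower, among them Hes1 (75.4 and 53.7 CPM, -0.49), and 1 higher. With equal cluster weights it was at -0.10 (percentile 0.02), still below the central range. Wnt signalling (-0.16; 8 of 9 lower, 0 higher) included Axin2 (20.4 and 14.8 CPM, -0.46), Fzd8 (-0.40) and Sfrp1 (284 and 219 CPM, -0.38). Cholesterol biosynthesis (-0.15; 10 of 15 lower, 0 higher) included Hmgcs1 (322 and 267 CPM, -0.27) and Insig1 (-0.37), but was at -0.01 with equal cluster weights and at 0.013 without the clusters of uneven share. Subtype transcription factors (-0.10; 13 of 26 lower, 6 higher) had Nfia (627 and 486 CPM, -0.37) and Emx2 (-0.33) lower and Bcl11b (86.0 and 124 CPM, 0.52) higher. With equal cluster weights Wnt signalling (-0.08; percentile 5.69) and these factors (-0.04; percentile 9.72) moved inside. Reelin signalling (-0.10), with Dab1 (-0.38) and Cdh2 (-0.25), and FMRP partners (-0.09), with Mtor (-0.34), Eif4ebp1 (-0.30) and Purb (0.31), were lower too. Mitosis was higher (0.06; 20 of 34 members, 0 lower), with Ube2c (672 and 819 CPM, 0.29), Aurka (0.21) and Hmmr (0.20), but was level with equal cluster weights (percentile 72.4). Those weights brought DNA replication below the central range (-0.10; percentile 0). They brought interferon response (0.21; percentile 100), heat shock (0.05), glycolysis (0.03), oxidative phosphorylation (0.03) and long adhesion genes (0.05) above it. Inside without these weights were actin regulators (-0.01), migration (-0.03), axon guidance (-0.03), the synapse (-0.02), DNA replication (0.01), p53 targets (-0.02), immediate early genes (-0.01), heat shock (0.04), glycolysis (-0.04), the unfolded protein response (-0.07), mitochondrially encoded transcripts (-0.02), oxidative phosphorylation (0.04), interferon response (-0.10) and long adhesion genes (-0.02).

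Within radial glia Bcl11b (10.7 and 28.3 CPM, 1.40) was higher, and Tesc (38.4 and 17.9 CPM, -1.10), Garem1 (-1.02) and Lrrc8b (-0.90) lower. Intermediate progenitors held more of the peptide transporter Slc15a2 (10.9 and 34.5 CPM, 1.66), Ifitm3 (0.96) and the imprinted Meg3 (44.5 and 84.7 CPM, 0.93), and less Nhlh2 (-1.16) and Tcf7l2 (-1.05). Dividing progenitors held more Zic1 (35.2 and 90.1 CPM, 1.36) and Tshz2 (1.22), and less of the amino acid transporter Slc7a5 (24.7 and 12.1 CPM, -1.03), asparagine synthetase Asns (23.1 and 11.9 CPM, -0.96) and Bhlhe22 (-0.98). Progenitor cluster 0 held more tubulin Tubb2a (33.9 and 103 CPM, 1.60) beside its excess of Cyfip2 (11.6 and 55.1 CPM, 2.25), and less Grk3 (-1.17), Kcnn2 (-1.12) and the lipid exporter Abca1 (-1.12).

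Cajal-Retzius cells were few, with 38 and 59 cells, and their ratios are the least certain of the 4 main comparisons. Of 3677 measured genes 85 were at least 1.5-fold higher and 114 lower, and 121 and 101 with a median-of-ratios size factor. Reln, the signal these cells secrete, was at 5511 and 4422 CPM (-0.32), and Cyfip2 at 116 and 154 CPM (0.42; 0.04 to 0.80). Higher were the heparan sulphate enzyme Ndst4 (log2 ratio 2.04), the protocadherin Pcdh11x (84.8 and 329.8 CPM, 1.96), the thalamic and septal factor Lhx9 (21.8 and 81.3 CPM, 1.90), Resp18 of secretory granules (1.74), the dendrite regulator Btbd3 (36.0 and 105 CPM, 1.55), Sox9 (36.0 and 101 CPM, 1.5), Mgat4c (1.14), Sorbs2 (1.04), the sodium pump regulator Fxyd7 (1.01), Gsdme (0.98), Phc2 (0.95) and Synj2bp (0.93). Lower were the Wnt activator of the cortical hem Rspo3 (127 and 32.9 CPM, -1.95), Fibcd1 (150.3 and 44.8 CPM, -1.75), the potassium channel Kcnma1 (96.4 and 39.3 CPM, -1.29), the repressor Zbtb18 (93.8 and 38.4 CPM, -1.29), the hippocampal factor Zbtb20 (743 and 377 CPM, -0.98), Angpt1 (172 and 73.1 CPM, -1.24), the calcium channel subunits Cacna2d3 (148 and 74.9 CPM, -0.98) and Cacng7 (-1.0), Gadd45g (-1.01) and Eif2b5 (-1.02). Cck (-2.13) and Mef2c (-1.20) were lower too, with 49.4% and 60.0% of their wild-type counts in 1 cell. With cells thinned to 1000 UMIs only 6 genes passed the rule, and Eif2b5 (1.37) and Phc2 (-0.0498) reversed. Mef2c reversed with 2000 UMIs (0.057), the automatic doublet threshold (0.096) and no doublets left out (0.15).

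Of 18 lists in Cajal-Retzius cells 0 lay above and 4 below the central range, but 0 lay outside with thinned cells and 8 with a mitochondrial maximum of 5%. Wnt signalling (median -0.45; 4 of 6 lower, 0 higher) included Dkk3 (195 and 114 CPM, -0.77) and Ctnnb1 (592 and 386 CPM, -0.62). Subtype transcription factors (-0.39; 6 of 12 lower, 2 higher) included Nfia (-0.56) and, in the other direction, Tle4 (0.56), but their median was above 0 with the automatic doublet threshold (0.094) or no doublets left out (0.15). The p53 targets (-0.26; 2 of 8 lower, 0 higher) included Cdkn1a (100.2 and 64.9 CPM, -0.63) and Bbc3 (-0.64) as its lower members, and mitochondrially encoded transcripts (-0.17; 8 of 11 lower, 0 higher) mt-Nd4 (2418 and 1990 CPM, -0.28). Synaptic genes were inside the central range (-0.11; percentile 5.71), though Gria1 (-0.76), Gria4 (-0.75) and Slc17a6 (-0.74) were lower. Inside were also actin regulators (0.01), FMRP partners (-0.15), Reelin signalling (-0.08), migration (-0.02), axon guidance (-0.01), immediate early genes (0.14), heat shock (0.14), glycolysis (0.08), the unfolded protein response (0.12), oxidative phosphorylation (0.09), cholesterol (-0.09) and long adhesion genes (-0.01).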

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

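For the Cyfip2 pattern the test of neurons mixed with other cells was chosen before its result was seen, while the tests of free RNA and of a transcript from the targeted allele, and both tests for Ttr, were chosen after the results were seen.

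Cyfip2 stood out because its ratio ran in opposite directions between classes: the log2 ratio was -0.15 in excitatory neurons and -0.13 in GABAergic neurons, against 0.81 in progenitors and 3.66 in microglia. The difference between the classes was not tested, and no other library bears on it. Free RNA could bring neuronal tags into every droplet, but it adds at most 2.67 CPM of Cyfip2 in the knockout-labelled library, against 46.5 CPM in microglia, which excludes it as the main source. Neurons mixed with other cells would carry all abundant neuronal transcripts, yet the median of 20 such genes in microglia was 3.76% of their level in excitatory neurons (highest 7.34%; 3.39% in wild type), against 50.2% for Cyfip2, which excludes it too. A transcript of the targeted allele, for example one driven by an inserted promoter in every cell type, may give tags in every cell type. The prediction for that explanation, written after the results were seen, was that genes within 5 Mb stay within 0.1 of 0 in progenitors. Not all did, but none moved as much as Cyfip2 there, with a largest log2 ratio of 0.29 (Trim41). The test covers progenitors only, and in excitatory neurons Ebf1, among these genes, was at 0.89. A change in the regulation of Cyfip2 itself could also leave its neighbours unmoved, so the test cannot tell these explanations apart. Without read positions both stay open.

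Ttr and Ebf1 stood out in barcodes with fewer than 100 UMIs, which were not called as cells and serve as the profile of free RNA. Only named genes with at least 100 CPM there in both libraries were flagged. Ttr was at 1016 and 2070 CPM there (log2 ratio 1.03; 3301 and 7726 counts) and Ebf1 at 114 and 198 CPM (0.79), and these differences were not tested. Below that level other named genes were higher in these barcodes too, such as Dlx6os1 (0.80), Thsd7a (1.10), Tfap2d (1.35) and Zic1 (0.62). Others, such as Lmo3 (0.06), Npy1r (-0.10) and Cyfip2 (-0.06), were not. Ttr was also at least 1.5-fold higher in 12 of 14 classes of cells, with a median log2 ratio of 1.41. Free RNA may account for it: Ttr tended to be higher in classes with fewer UMIs per cell, with a rank correlation over the 14 classes of -0.85 in the knockout-labelled and -0.67 in the wild-type library, where classes are not replicates. Interneurons of the medial ganglionic eminence were highest in wild type, at 112 CPM, but at 31.5 CPM without their 5 highest cells. Expression by neurons stays open. After subtracting the profile under 100 UMIs, -1.45 CPM were left in excitatory neurons of the wild-type and 25.9 CPM in those of the knockout-labelled library. Under the profile from 100 to under 500 UMIs 6.90 and -5.38 CPM were left, so the direction turned with the profile. Choroid plexus in the dissected tissue could differ between the pools, which was not tested. Cluster 19, led by choroid plexus genes, was not more frequent in the knockout-labelled library (ratio 0.890, 0.727 to 1.09). Its cells with more than 5% of UMIs from Ttr were 15 and 10.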

How the results depend on the processing

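No paired analysis was possible because each label has 1 library, and no value comes from a test. A value therefore counts as moved when it leaves its counting interval, or for a count of genes when it differs more than 1.5 times. A list median has no counting interval. It counts as stayed when it shifts no further than from the middle to the edge of the central range of matched lists. A list median that stayed can therefore still return to the central range. With equal cluster weights actin regulators in excitatory neurons did so, from percentile 0.73 to 9.36. Equal cluster weights, leaving out clusters whose share differed at least 1.5 times, and subtraction of the free RNA profile from 100 to under 500 UMIs were chosen after seeing the data. Of 74 values for Cyfip2, 67 stayed, 7 moved and 0 reversed. Of 521 list medians 475 stayed, 35 moved and 11 reversed, and of 1320 values of named genes 1100 stayed, 205 moved and 15 reversed. Of 44 share ratios 38 stayed and 6 moved, all in their direction. Of 68 counts of genes 43 stayed, and of 68 counts of lists 58. The excess of Ttr in excitatory neurons ranged from a log2 ratio of 1.35 to 1.85 in the settings that gave a ratio, which leaves out both subtractions of free RNA. No value was possible for Cyfip2 in thinned microglia, for Ttr in excitatory neurons after subtraction of either free RNA profile, and for Ttr in progenitors under that from 100 to under 500 UMIs, because nothing was left in 1 library. Subtracting free RNA and the median-of-ratios size factor moved no count and reversed no value that had a ratio. With the profile from 100 to under 500 UMIs subtracted, 6.90 CPM of Ttr were left in wild-type excitatory neurons. In the knockout-labelled library -5.38 CPM were left, so the excess of Ttr was gone. For the values below the cause was not tested, except that a lower minimum lets in more genes and thinning leaves fewer counts.

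The reported counts of genes are 15, 41, 29 and 199 in excitatory neurons, GABAergic neurons, progenitors and Cajal-Retzius cells, and those of lists outside the central range 9, 11, 7 and 4. With 500 UMIs and 250 genes progenitors had 48 genes and 12 lists. With 2000 UMIs excitatory neurons had 8 genes and a share ratio of 0.838, GABAergic neurons 7 lists, and Ttr in progenitors (-2.22) and Mef2c in Cajal-Retzius cells (0.057) reversed. With a mitochondrial maximum of 5% excitatory neurons had 7 genes and a share ratio of 0.848, Cajal-Retzius cells 8 lists, and Thsd7a in excitatory neurons reversed (-0.087). With no doublets left out Cyfip2 in excitatory neurons was at -0.20, progenitors had 14 lists, and in Cajal-Retzius cells subtype factors (0.15) and Mef2c (0.15) reversed. With the automatic Scrublet threshold excitatory neurons had 23 genes, progenitors 47 genes and 11 lists, and in Cajal-Retzius cells subtype factors (0.094) and Mef2c (0.096) reversed.

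At resolution 0.5 Cyfip2 was at -0.24 in excitatory neurons and 0.55 in progenitors, excitatory neurons had 26 and GABAergic neurons 24 genes, and the GABAergic share ratio was 1.17. Subtype factors (-0.064), Nap1l5 (-0.023) and Hap1 (-0.31) in GABAergic neurons and mitosis in progenitors (-0.0091) reversed. At resolution 2 share ratios were 0.863 for excitatory neurons and 0.973 for progenitors, which had 11 lists, and Nrp2 in excitatory neurons (-0.056) and mitosis in progenitors (-0.0059) reversed. With genes centred within each library excitatory neurons had 8 genes and a share ratio of 0.863, and Thsd7a reversed there (-0.16). Without mitochondrial, haemoglobin and ribosomal protein genes GABAergic neurons had 7 lists.

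With cells thinned to 1000 UMIs Cyfip2 was at -0.068 in excitatory and -0.33 in GABAergic neurons, the counts of genes were 37, 132, 124 and 6, and Cajal-Retzius cells had 0 lists. Oxidative phosphorylation in GABAergic neurons (-0.033) and, in Cajal-Retzius cells, Phc2 (-0.0498) and Eif2b5 (1.37) reversed. With a minimum of 10 CPM there were 27, 70 and 81 genes in excitatory neurons, GABAergic neurons and progenitors. With no filter but 1 count there were 593, 601, 584 and 703 genes and 11 lists in progenitors, and migration in GABAergic neurons reversed (0.011).

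With equal cluster weights excitatory neurons, GABAergic neurons and progenitors had 6, 22 and 7 genes, GABAergic neurons had 6 lists, and subtype factors in GABAergic neurons (-0.027) and mitosis in progenitors (-0.00036) reversed. Without the uneven clusters Cyfip2 was at -0.052 over all cells and 0.67 in progenitors, and these 3 classes had 9, 15 and 18 genes. Thsd7a in excitatory neurons (-0.15), subtype factors (-0.018) and Hap1 (-0.21) in GABAergic neurons, and cholesterol (0.013), Scrg1 (0.91) and Id3 (0.42) in progenitors reversed.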

Other observations

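The depth test of the shares was chosen before its result was seen, and the test of dissection or genotype after.

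Microglia carried the WAVE complex in its form of blood cells. Cyfip1, their main Cyfip gene, was at 277 and 299 CPM, Wasf2, the WAVE protein of non-neuronal cells, at 196 and 238 CPM (log2 ratio 0.29) and Nckap1l, the Nckap1 paralogue of blood cells, at 109 and 87.1 CPM. Among the named genes of microglia the replication histone Hist1h1b was at 15.7 and 89.8 CPM (2.52). Ebf1 (5.02) and Cxcl9 (2.61) were higher with 50.9% and 93.2% of the knockout-labelled counts in 1 cell. Cstdc4, Cstdc5 and Retnlg were lower by at least 116-fold, 107-fold and 100.1-fold by the floor of 3 counts, with all wild-type counts in 1 cell. A large share of the counts of 1 library also lay in 1 cell for Gng8 (2.08; 91.1%) and Nts (-2.44; 50.0%) in interneurons of the medial ganglionic eminence, Mia (3.51; 56.8%) in radial glia, Id3 in progenitor cluster 0 (1.60; 52.5%), Rspo3 in intermediate progenitors (-2.61; 49.6%), and Nts (1.96; 46.5%) in cluster 23. In that cluster Tac2 was lower (-1.63), with 82.9% of its knockout-labelled counts in 1 cell, and Tmem176b (1.45) and Tmem132c (-1.47) were also named.

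Ttr was among the named genes of 9 further classes: upper-layer neurons (2.03, with 20.8% of the knockout-labelled counts in 1 cell), cluster 23 (2.02), dividing progenitors (1.67), interneurons of the caudal or lateral eminence (1.56), cluster 12 (1.53), radial glia (1.43), deep-layer neurons (1.39), cluster 3 (1.33) and migrating neurons (1.25). No gene differed 1.5-fold in the same direction in all 14 classes. The macrophage chemokine Pf4 had ratios past 1.5-fold in all 9 classes where it had at least 20 counts, 344 in total, with log2 ratios from 1.31 to 4.23, and somatostatin, Sst, in all 8 (0.67 to 2.77), though over the 14 classes the interval of Sst lay above 0 in only 6. In barcodes with fewer than 100 UMIs Pf4 was at 59.7 and 188 CPM and Sst at 49.8 and 71.5 CPM. Arc and Tac2 had lower ratios in all 4 classes with enough counts. The unnamed transcript Gm47283, annotated on chromosome Y, was at 201 and 121 CPM over all cells (-0.73; 19500 and 13227 UMIs), with its interval below 0 in 14 of 14 classes, and Mid1 at 39.1 and 27.0 CPM (-0.54), in 13 of 14. Xist was at 1567 and 1676 CPM, and Ddx3y and Eif2s3y had 0 UMIs in both libraries, as in pools of mainly female embryos; Kdm5d had 7 and 7 UMIs and Uty 5 and 10. Among the Y-annotated transcripts looked up, only Gm47283 (90784738 to 90816464) was abundant, and it is not taken as a mark of male cells. Mid1, annotated on chromosome X (169685199 to 170005736), was lower beside it, and the cause was not tested. Cluster 19, of 179 and 218 cells, stayed unnamed: choroid plexus genes lead it, but Ttr made up more than 5% of UMIs in only 15 and 10 of its cells. Cluster 28 had 16 and 2 cells, with the pineal genes Tph1 and Crx.

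Among named clusters of at least 100 cells in each library, clusters 2, 17 and 20 differed most in share. A depth gap between the libraries could shift cells between clusters. Among cells of at least 5000 UMIs the ratio of cluster 20 was 3.76 (3.01 to 4.74), of cluster 2 2.01 and of cluster 17 2.00. Shallow cells are therefore not the source of these ratios. Cells were not brought to equal depth and clustered again, so a shift between clusters by depth is not excluded. Different tissue in the dissection, or the genotype, may give the difference. The share ratio of dividing cluster 14, with ganglionic eminence markers, was 1.71 times that of cluster 7, with cortical markers, while eminence progenitor cluster 0 was at 1.14 (0.909 to 1.43). The prediction, written after the results were seen, also asked for a lower share in every excitatory cluster and a higher one in every GABAergic cluster. This failed in 2 of 10 and 2 of 7 clusters, with cluster 20 among them. Dissection and genotype shared 1 prediction, which could not tell them apart, and both stay open with 1 pool per label.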
